A study of Saccharomyces cerevisiae with 60 samples.

How the data were processed

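RNA from 9 strains of Saccharomyces cerevisiae was compared with reference pools on arrays of 2 colours. Per the labels, total RNA from exponentially growing cells was extracted with hot phenol and chloroform, labelled by reverse transcription with amino-allyl dUTP and coupled to Cy3 or Cy5. Per the labels, arrays were scanned with a GenePix 4000A scanner and read with GenePix 4.0 software, and bad spots were marked from the image. Which dye lay in which channel, and any normalization, are not given in the sources used here. The deposited values were ratios, and their log2 was taken here: 60 arrays of 6144 rows, with 0 missing values. Of the deposited ratios under 10, 100% were within 0.00001 of a number with 3 decimals. Array medians of log2 ran from -0.77 to 1.16 and their median absolute deviations (MAD) from 0.15 to 0.83, so the deposited arrays were neither centred nor scaled.

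Gene names were taken from the platform rows and matched to the table of R64 genes by identifier. This matched 5536 rows and left 5 with the name given by the platform. Of all rows, 5541 had 1 gene, 0 several and 603 no listed gene. The rows of 17 genes with more than 1 row were averaged, which gave 5524 genes. Rows with no listed gene were left out of the counts. Near-identical copies (CUP1-1 and CUP1-2, the ASP3 genes, ENA1 and ENA2, FLO1 and FLO9, and Ty reading frames) were kept under their own names but share hybridization.

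Each array was centred on its median log2 ratio. Strain arrays were turned so that values read strain over pool, and pool arrays so that they read copper over rich medium. The turning used the channel order of the labels and the ratio directions inferred from the data. For strain arrays the direction was tested on the 200 rows that varied most, since the linear ratios of the 9 strains to their common pool must average 1. For pool arrays it rests on the induction of CUP1 by copper. The number of arrays limits the precision, and depth is not defined for these values.

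The 54 strain arrays were fitted with limma 3.58.1 in R 4.3.3 as 18 group means (9 strains in each of 2 media, 3 arrays each) and 1 channel effect per gene. The 6 pool arrays were fitted with a mean and a channel effect. Moderated tests were used with Benjamini-Hochberg adjustment over 5524 genes at 0.05. The comparisons were copper against rich medium in the pools, an F-test over the 9 strains in each medium, an F-test of the interaction of strain and medium, and each strain against the mean of the other 8 in copper. The contrast of each strain in rich medium and the response of each strain to copper were computed for values beside these. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for preparation and figures.

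There were 25 gene lists with 818 members, of which 785 were measured. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and for F-tests with Fisher's exact test (two-sided) against all other genes. Genes were named by rule. The rule took the 10 highest and 10 lowest in the pools among those past the threshold with the same sign on every array, the 15 with the largest range in each F-test, and the 2 highest and 2 lowest per strain whose replicates agreed in side. It also took up to 4 genes per list, and CUP1-1, CUP1-2, CRS5, SOD1, CTR1, FRE1, HO, STE2, STE3 and MF(ALPHA)1. Genes named outside this rule, such as those in the list of other observations, were chosen after their values were seen. The comparisons, tests, lists, rule and most alternatives were chosen before the data were examined.

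Alternatives were deposited values without centring, arrays scaled to an equal MAD, no channel effect, a robust empirical Bayes step, each row on its own, only the arrays of that medium, a replicate block, and leaving out each array or each replicate number in turn. A pair of alternatives for spot position was chosen after seeing the data. The first subtracted a running median of 15 by 15 spots from each array, with spots laid out from the row numbers as 16 blocks of 384 (16 rows by 24 columns). The second centred each array within the 16 blocks. The layout is inferred from the periodicity of the values: component 1 of the centred arrays held 34.1% of the variance, with an autocorrelation of 0.914 between neighbouring rows, 0.877 between rows 24 apart and 0.912 between rows 1536 apart. The running median removed between 6.27% and 72.2% of the variance of an array, with a median of 39.3%. The fits were tested on simulated data with 200 changed genes of 5524. Noise was normal and independent for each gene and array, with the residual spread of that gene. There was no spot trend, no noise shared between arrays and no difference in spread between arrays. All 200 genes of a run changed by the same size, and in the strain runs only in S288C in copper. Differences spread over several strains were not simulated. Recovery in the real arrays may therefore differ.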

Results

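Gene expression was measured on 60 arrays of 2 colours in 9 strains of budding yeast, each grown exponentially in rich medium and in medium with copper sulfate. S288C is the common laboratory strain. YPS163 is an isolate from oak woodland, and the other 7 strains carry M numbers, which are known as vineyard isolates. These origins are background and are not given in the labels. Each strain was hybridized in 3 replicates per medium against a reference pool, the combined RNA of all 9 strains in that medium, which made 54 strain arrays. The other 6 arrays compared the copper pool with the rich medium pool directly. The comparisons ask which transcripts change in copper, which differ among natural isolates, and whether the strains respond to copper in different ways. The number of arrays limits the precision. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

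The table held 6144 rows without missing values. Of these, 5541 had 1 gene name, 0 had several and 603 had none, and the named rows covered 5524 genes. Array medians ran from -0.77 to 1.16 on the log2 scale, so the arrays had not been centred, and each was centred here. The direction of the ratios is not stated. In a pool of all 9 strains the linear ratios of strains to pool must average 1, and this held with channel 1 over channel 2: the median absolute log2 of the mean ratio was 0.11 in copper and 0.12 in rich medium, against 0.38 and 0.39 for the opposite order. In the 6 pool arrays the values likely run as channel 2 over channel 1. The basis is CUP1-1, the copper-binding metallothionein gene, which copper is known to induce and which was 5.87 higher in the copper pool in this direction (mean of 6 arrays, SD 2.44). With the sign turned, every rise in the pools would be a fall. This direction is opposite to that of the strain arrays, and the reason is unknown. As deposited, 1 of 8 pairs of pool arrays with opposite channel order correlated below 0 (median 0.28), against 27 of 36 pairs of strain arrays. By this measure alone the pool arrays would be left unturned. After turning, however, CUP1-1 lay between 3.45 and 8.92 on all 6 arrays. The scale and the direction are thus inferred, and the treatment of spots marked as bad remains unknown.

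Channel order left a strong mark on the pool arrays. Pairs of pool arrays with opposite order had a median correlation across genes of -0.28 after turning and pairs with the same order 0.34, and 949 genes passed the test for a channel effect, which the model removes gene by gene. The median size of this effect, 0.28, was larger than the median copper effect of 0.18. Among strain arrays of the same order and medium but different strains, 48 of 352 pairs had a correlation under -0.3, the lowest -0.60. With a running median over spot positions subtracted, 0 pairs did, the lowest being -0.29. All 54 arrays then correlated above 0 with their own strain in the other medium over 200 genes, the lowest r being 0.34. Of the 54 arrays, 47 correlated best with their own strain, against 35 before the subtraction. These correlations are across genes, which are not independent replicates.

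In the reference pools, copper raised the metallothionein genes CUP1-1 (log2 5.38 ± 0.53, SE, n = 6 arrays, adjusted p = 1.61e-04) and CUP1-2 (5.35 ± 0.52), near-identical copies whose transcripts share hybridization and cannot be separated here. The small heat shock gene HSP12 rose by 3.15 ± 0.19, the aldehyde dehydrogenase gene ALD3 by 2.11 ± 0.18 and the hexokinase gene HXK1 by 2.05 ± 0.22. MSC1 (1.92 ± 0.17), the glucokinase gene GLK1 (1.72 ± 0.20), the phosphoglucomutase gene PGM2 (1.51 ± 0.16) and the catalase gene CTT1 (1.46 ± 0.16) rose as well. ZRT1, encoding the high-affinity zinc transporter, was the gene that fell most, with -1.99 ± 0.30 (adjusted p = 0.004). The water channel gene AQY2 fell by 0.95 and FRE1, encoding a reductase of copper and iron at the cell surface, by 0.86. All of these lay on the same side of 0 on every array, except FRE1. CTR3, a copper transporter gene, had a value of -2.13 ± 0.62, with 4 of 6 arrays below 0, but did not pass the test (adjusted p = 0.142). The second metallothionein gene CRS5 had 0.34 ± 0.24 (adjusted p = 0.520).

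Of the copper homeostasis list, 3 of 14 genes rose, 1 fell and 10 did not pass the test. SOD1, the copper and zinc superoxide dismutase gene, rose by 1.26 beside the CUP1 copies. Adjusted over the list alone 3 rose and 2 fell, and camera gave adjusted p = 0.0208 for a rise (adjusted p = 0.396 with an estimated correlation). In the iron uptake regulon 2 of 27 genes rose, the multicopper oxidase gene FET3 by 1.41 and its partner permease gene FTR1 by 1.11. Adjusted over the list alone the counts were the same. In the zinc regulon 1 of 13 genes, ZRT1, fell, and camera gave adjusted p = 0.0073 for a fall (adjusted p = 0.258 with an estimated correlation). In the sulfate assimilation and methionine list MET17, which makes homocysteine, rose by 1.19, and 30 of 31 genes did not pass.

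The trehalose, glycogen and general stress list held 13 of 27 genes that rose and 0 that fell, among them ALD3, HXK1, PGM2 and the trehalose synthase gene TPS1 (1.04). Adjusted over the list alone 15 rose and 1 fell, and camera called the rise with an assumed correlation (adjusted p = 2.57e-18) and with an estimated correlation (adjusted p = 0.029). The latter call was lost at adjusted p = 0.0539 with spot position corrected. The list median then went from 0.78 to 0.70, and 13 genes still rose. Of 30 heat shock and chaperone genes 11 rose and 0 fell, and 19 rose adjusted over the list alone. They include HSP12, the Hsp70 genes SSA1 (1.51) and SSA4 (1.24), their cochaperone gene SIS1 (1.36) and the disaggregase gene HSP104 (1.16). The camera call (adjusted p = 4.49e-19) was lost at adjusted p = 0.106 with an estimated correlation. Of 37 oxidative stress genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone, including the peroxiredoxin gene AHP1 (1.14) and the aldose reductase gene GRE3 (1.43) on the rise. Camera gave adjusted p = 6.56e-04 (adjusted p = 0.414 with an estimated correlation).

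No single gene passed among 52 cytosolic ribosomal protein genes (median log2 -0.17) or 63 ribosome biogenesis genes (median -0.27), and none did adjusted over each list alone. Camera called both lower (adjusted p = 0.00935 and 1.42e-05), and both calls were lost with an estimated correlation (adjusted p = 0.681 and 0.639). The ribosomal protein call, with spot position corrected, was lost with an assumed correlation as well (adjusted p = 0.0812). The 40 genes of the respiratory chain and ATP synthase had a median of 0.25. Of them 0 passed over all genes and 6 rose adjusted over the list alone, with camera adjusted p = 1.15e-07 (adjusted p = 0.502 with an estimated correlation). In the ergosterol list the squalene epoxidase gene ERG1 fell by 0.77, the list median was -0.23 and camera gave adjusted p = 0.00176 (adjusted p = 0.583 with an estimated correlation). Camera called none of the remaining lists. Once spot position was corrected it called the sulfate list and the TCA cycle list higher with an assumed correlation (adjusted p = 0.00123 and 0.0212) but not with an estimated correlation (0.264 and 0.420). Among the lists not called, 1 gene rose in the glycolysis list (median -0.07, against a mean of 0.09), 1 fell in the TCA cycle list (CIT3 with -0.76, median 0.04, 5 higher and 1 lower adjusted over the list alone) and 1 fell in the ion and water transport list (median -0.13). CIT3 passed in 3 of 13 settings (adjusted p up to 0.982) and did not with spot position corrected. No gene passed in the lists for hexose transport (median 0.03), amino acid synthesis (0.02), nitrogen catabolite repression (-0.06), vitamins and purines (-0.10), the phosphate regulon (-0.24), flocculation and cell wall (0.07), anaerobic genes (-0.01), multidrug resistance (-0.11), histones and cell cycle (-0.01), meiosis (0.03, against a mean of -0.04) and mating type (0.07). Adjusted over the list alone, 1 gene was higher and 1 lower in both the anaerobic and the cell wall list. The camera direction followed the mean in glycolysis (up) and meiosis (down), opposite to the sign of the median.

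Over all 5524 genes 78 passed the limma test, 65 higher and 13 lower in copper, with 806 at an unadjusted p under 0.05 where chance gives 276.2. In simulated data with independent noise this comparison recovered 73.0% of changes of log2 1 and 98.0% of changes of log2 2, which may not hold for the real arrays. Leaving out pool array 1, 3 or 5 brought the count to 31, 15 and 41, with 2, 0 and 3 genes lower. Without array 2, 4 or 6 the lower genes numbered 12, 17 and 15. Without the channel effect it was 21, with 1 lower, and with arrays scaled to an equal spread 27, with 2 lower. In deposited values without centring 93 genes were higher and 7 lower. The 9 genes from CUP1-1 to CTT1 that open this comparison passed in every setting. The calls of ZRT1 and SSA1 ended without array 3 (adjusted p = 0.157 and 0.0511), those of SSA4 and MET17 without array 1 or with scaled arrays (up to 0.187 and 0.0671), that of FET3 with scaled arrays (0.0599), those of GRE3 and SIS1 without the channel effect (0.385 and 0.0776) and that of AHP1 without array 3 or the channel effect (up to 0.328). SOD1 did not pass without array 1 or 3, scaled arrays or the channel effect (up to 0.233), FTR1 without array 1, 2, 3 or 5, scaled arrays or the channel effect (up to 0.367), and AQY2 without array 1, 2 or 3 or the channel effect (up to 0.275). FRE1 and ERG1 passed in 5 of 13 settings, and neither passed without array 1, 2, 3 or 6, nor FRE1 without array 5 (adjusted p up to 0.762 and 0.621). With a running median over spot positions subtracted 88 genes passed, 59 of them shared.

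**Figure D1:**
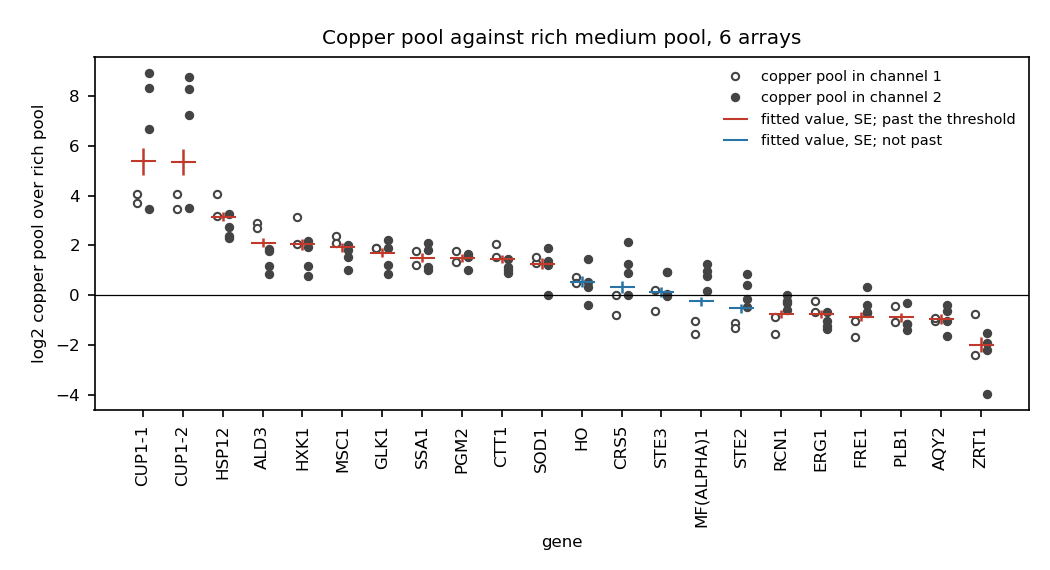
Log2 ratio of copper pool over rich medium pool for genes named by a fixed rule, with the 6 arrays as points by channel order and the fitted value with its SE as a bar. CUP1-1 and CUP1-2 had the highest fitted values, 5.38 and 5.35, and ZRT1 the lowest, -1.99.

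Among the 9 strains in copper the gene with the largest range was YGR201C, an uncharacterized gene resembling translation elongation factor subunits, with 8.11 between M32 and M14 (adjusted p = 8.45e-09). PHO84, the high-affinity phosphate transporter gene, ranged over 6.33 between S288C and M13. The mitochondrially encoded ATP synthase genes ATP8 (6.01) and ATP6 (3.88) were highest in YPS163 and lowest in M34. The asparaginase copies ASP3-2 (4.58), ASP3-1 (4.45) and ASP3-3 (4.15) peaked in M32, and as near-identical copies with shared hybridization they count as uncertain single genes. YHB1, a flavohemoglobin gene for nitric oxide detoxification, ranged over 4.48 between M13 and M32. MRH1, a plasma membrane protein gene, ranged over 3.93 between S288C and M14, the sulfur transferase gene RDL1 over 3.84 between M32 and YPS163, and the sulfite pump gene SSU1 over 3.35 between M5 and YPS163. MET6, the methionine synthase gene, ranged over 3.32 between M22 and M13. Ty retrotransposon reading frames, many near-identical copies, such as YBL005W-B (4.15), YPL257W-B (4.03) and YJR027W (3.89), made up 32 of the genes past the threshold and mitochondrially encoded genes 7, in a tally made after the calls were seen.

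The copper homeostasis genes did not pass across strains: CUP1-1 ranged over 2.25 (adjusted p = 0.855), CRS5 over 1.65 (0.327), FRE1 over 1.6 (0.0534) and SOD1 over 1.24 (1.00). CRS5 and FRE1 passed once a running median over spot positions was subtracted (adjusted p = 0.00643 and 0.0196). Of 14 genes in that list 0 passed and 1 did adjusted over the list alone. In single strains camera called the list higher in M14 (adjusted p = 0.0194, median 0.17) and lower in S288C (adjusted p = 0.0282, median -0.08, 2 genes lower adjusted over the list alone). Both calls were lost with an estimated correlation (adjusted p = 0.0586 and 0.078). Of the nitrogen catabolite repression list 4 of 30 genes passed, all ASP3 copies, which share hybridization and may be 1 signal. Of the phosphate regulon 3 of 19 passed, PHO84, SPL2 (3.04) and VTC1 (2.50), with adjusted p = 0.0300 by Fisher's exact test against all other genes. VTC1 passed in 11 of 39 settings (adjusted p up to 0.941). Adjusted over each list alone 4 and 4 genes passed. In the heat shock list 3 genes passed (BTN2, KAR2, SIS1), in the respiratory chain list 2 (CYC1, RIP1), in the sterol list 2 (ERG11, HMG1), in the iron list 2 (ARN2, ENB1), in the flocculation and cell wall list 2 (DSE2, FLO9) and in the sulfate list 1 (MET6), with an adjusted p of 0.0747 or more by the same test. ARN2 passed in 15 and SIS1 in 26 of 39 settings (adjusted p up to 1.00 and 1.00), ASP3-4, CYC1, RIP1 and FLO9 in 34, BTN2, ENB1, ERG11 and HMG1 in 35 and KAR2 in 37. After position correction genes of 4 of these lists passed more often than other genes by Fisher's exact test: 11 of 40 respiratory chain genes (adjusted p = 3.67e-06), 7 of 30 heat shock genes (7.86e-04), 6 of 31 sulfate genes (0.00554) and 6 of 33 cell wall genes (0.00626), the last with FLO1 and FLO9, which share sequence, among them. The phosphate regulon had 5.96e-04. The test over 9 strains passed 80 of 5524 genes, with 326 at an unadjusted p under 0.05. Without replicate 1 of every strain 18 passed and without replicate 3 of every strain 51. The ranges of YGR201C, PHO84, ATP8, MRH1, YJR027W, YPL257W-B and YER138W-A passed in all 39 settings. Leaving out a replicate number of every strain ended the calls of YHB1, RDL1 and SSU1 (numbers 1 and 2, adjusted p up to 1.00, 0.165 and 0.497), ASP3-1 (numbers 1, 2 and 3, 0.726), ATP6, ASP3-2 and SPL2 (number 1, 0.20, 0.805 and 0.0937), ASP3-3 (number 2, 0.0767), YBL005W-B (numbers 1 and 3, 0.384) and MET6 (number 3, 0.0693). SSU1 also ended without YPS163 copper replicate 2, ASP3-2 without M32 copper replicate 1, and ASP3-1 without M32 copper replicate 1 or 2 or S288C copper replicate 2. With arrays scaled to an equal spread 244 passed, with only the copper arrays in the fit 143, and with spot position corrected 208, of which 79 were shared. In simulated data with independent noise and a change in 1 strain, 0.5% of differences of log2 1 and 89.5% of log2 2 were recovered.

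**Figure D2:**
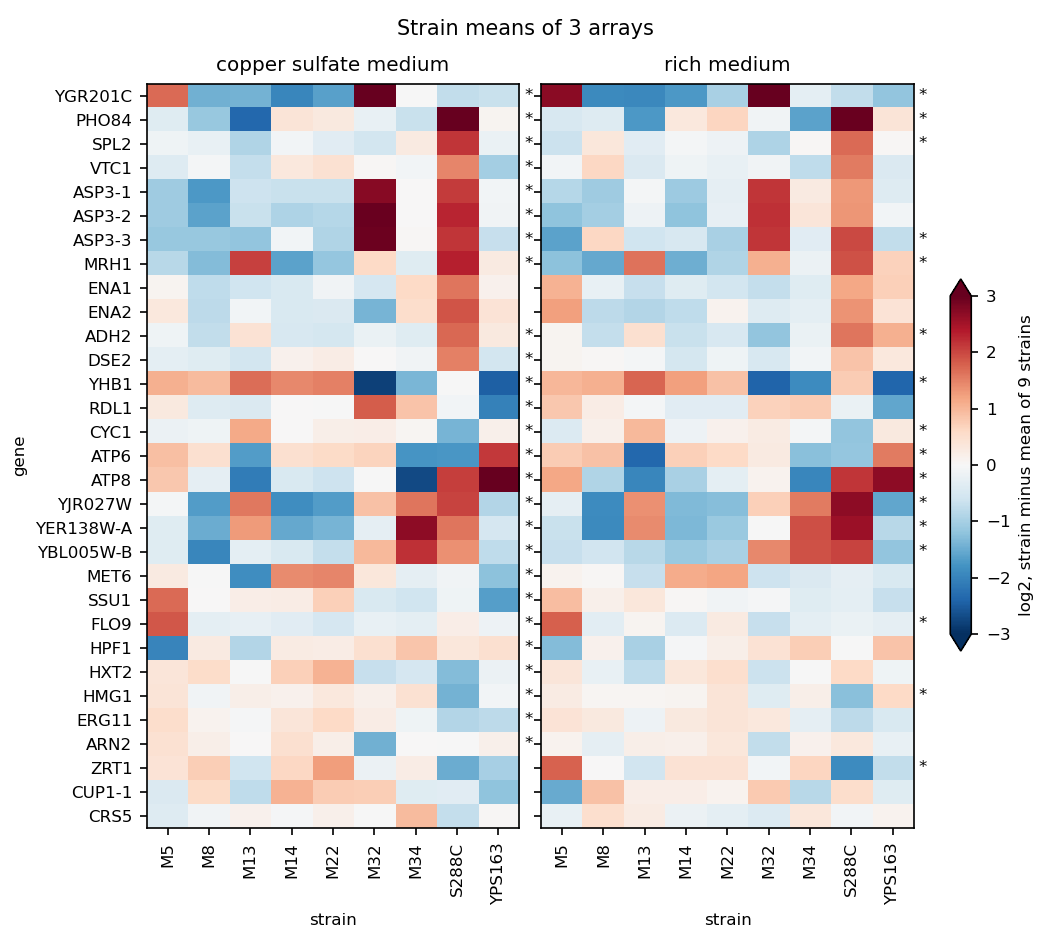
Mean log2 value of each strain over 3 arrays minus the mean of the 9 strains for selected genes in copper and rich medium, with an asterisk where the test over strains passed and colours saturating beyond 3. YGR201C stands out in M32, PHO84 in S288C and ATP8 in YPS163 in both media.

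With centred values S288C differed from the other 8 strains in more genes than any other strain in copper: 69 passed, 52 higher and 17 lower, with 291 at an unadjusted p under 0.05. Without replicate 2 of every strain it did not lead, with 28 genes against 34 in YPS163 and 30 in M32. The direction depends on centring: in deposited values without it 60 passed, 9 higher and 51 lower, of which 26 were shared. PHO84 was higher by 4.47 ± 0.37 (SE, n = 3 arrays, adjusted p = 1.31e-11), MRH1 by 2.62 ± 0.34, SPL2, a regulator of low-affinity phosphate uptake, by 2.42 ± 0.28, and DSE2, a daughter-cell gene for septum breakdown, by 1.71 ± 0.22. The alcohol dehydrogenase gene ADH2 was higher by 1.94 ± 0.32. HMG1, which makes mevalonate for sterols, was lower with -1.60 ± 0.23, YOL014W with -1.95 ± 0.28 and the cytochrome c gene CYC1 with -1.6 ± 0.30. Among further genes, the chitinase gene CTS1 was higher by 1.55, the polyphosphate synthesis genes VTC1 and VTC4 by 1.66 and 1.39, the sodium pump copies ENA1 and ENA2 by 1.81 and 2.13 (uncertain, shared hybridization), and the asparaginase copy ASP3-3 by 2.40. The hexose transporter gene HXT2 (-1.46), the sterol genes ERG5 (-1.11) and ERG11 (-1.0), the glutamate dehydrogenase gene GDH1 (-1.14) and ATP6 (-1.97) were lower. Of the 52 higher genes 25 were Ty reading frames, counted after the calls were seen.

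In S288C 7 of 19 phosphate regulon genes were higher and 0 lower, 11 adjusted over the list alone, and camera gave adjusted p = 1.63e-10 with an estimated correlation (2.72e-08 with spot position corrected). In the flocculation and cell wall list 4 of 33 were higher, 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00971 with an estimated correlation). Of 30 ergosterol genes 4 were lower, 12 adjusted over the list alone (adjusted p = 0.00275 with an estimated correlation). Nitrogen catabolite repression genes were called higher (1 of 30 by itself, 4 adjusted over the list alone, all ASP3 copies, adjusted p = 0.00401 with an estimated correlation). With spot position corrected the median of this list went from 0.21 to 0.04 and this call was lost (adjusted p = 0.105), while those of the cell wall and ergosterol lists held (both 0.0338). The ribosomal protein list had a median of -0.40 without a single gene past the test, and its camera call was lost at adjusted p = 0.20 with an estimated correlation. Respiratory chain genes were split, 1 higher and 3 lower, 2 and 6 adjusted over the list alone, and the call of a fall was lost at adjusted p = 0.103 with an estimated correlation. Other camera calls were the ribosome biogenesis, amino acid and vitamin lists (lower) and the stress, TCA cycle and ion transport lists (higher), lost at adjusted p = 0.078 or more with an estimated correlation. Leaving out S288C replicate 1, 2 or 3 brought the count of genes to 21, 18 and 32, the last with 19 higher and 13 lower. PHO84, MRH1, SPL2, DSE2, HMG1 and YOL014W passed in all 15 settings, and ADH2 in all but the fit without replicate 1 of every strain (adjusted p = 0.102). In deposited values without centring the median of all genes in this contrast was -0.48, and the calls of ASP3-3, CTS1, ENA1, ENA2, VTC1 and VTC4 ended. In the other strains this median was 0.11 in M5, 0.14 in M13 and M14, -0.26 in M22, 0.24 in M32 and 0.15 in M34. CYC1 and GDH1 ended without replicate 1 or 2 (adjusted p up to 0.126 and 0.311). Without each of the 3 replicates in turn the calls of CTS1, VTC1, VTC4, ENA1, ENA2, ASP3-3, HXT2, ERG5, ERG11 and ATP6 ended, and those of ERG5 and ATP6 also without the channel effect (adjusted p up to 0.223, 0.189, 0.515, 0.515, 0.198, 0.403, 0.339, 0.448, 0.414 and 0.270). With arrays scaled to an equal spread 127 genes passed, with the copper arrays only 111, and with spot position corrected 133, 91 higher and 42 lower, with all 69 among them. In simulated data with independent noise 47.0% of differences of log2 1 between a strain and the others and 99.0% of log2 2 were recovered.

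In M32 YGR201C was 6.94 ± 0.62 higher than in the other 8 strains (adjusted p = 1.25e-10) and passed in all 15 settings. The asparaginase copies ASP3-1, ASP3-2, ASP3-3 and ASP3-4 were higher by 3.06, 3.34, 3.32 and 2.85. The flavohemoglobin gene YHB1 was lower with -3.16 ± 0.71, the uncharacterized gene YIL089W with -1.95 ± 0.41 and the siderophore transporter gene ARN2 with -1.63 ± 0.29. In the nitrogen catabolite repression list 4 of 30 genes, the ASP3 copies, were higher, and adjusted over the list alone 5 were higher and 2 lower. Camera called the stress, ribosomal protein, ribosome biogenesis and glycolysis lists higher and the cell wall list lower, and all 5 calls were lost at adjusted p = 0.710 or more with an estimated correlation. The count was 12 genes, 7 higher and 5 lower (298 at an unadjusted p under 0.05). It moved to 1, 41 and 38 without M32 replicate 1, 2 and 3, with 1 higher and 0 lower, 4 higher and 37 lower, and 9 higher and 29 lower. Of the named genes YHB1 and ASP3-1 lost their calls without replicate 1 or 2 (adjusted p up to 1.00 and 1.00), and ASP3-2, ASP3-3, ASP3-4, YIL089W and ARN2 without replicate 1 (1.00, 0.713, 1.00, 1.00 and 1.00). With only the copper arrays ASP3-1, ASP3-2, ASP3-4 and YIL089W did not pass, and YIL089W did not without centring. Without replicate 1 of every strain, YGR201C alone of these passed. The split of higher and lower genes was 7 and 2 without centring, 31 and 49 with arrays scaled to an equal spread, and 25 and 31 with spot position corrected.

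In M13 the phosphate transporter gene PHO84 was lower with -2.65 ± 0.37 (SE, adjusted p = 4.73e-05), ATP8 with -2.37 ± 0.48 and the methionine synthase gene MET6 with -2.10 ± 0.42. MRH1 was higher by 2.31 ± 0.34, the Ty frame YDR034C-C by 2.15 ± 0.39, the drug pump gene PDR15 by 1.6 ± 0.31 and CYC1 by 1.27 ± 0.30. In the respiratory chain list 1 of 40 genes was higher by itself, 7 adjusted over the list alone, and the list had a median of 0.47 (camera adjusted p = 0.00104 with an estimated correlation). The sulfate assimilation list was lower (1 of 31 genes, 3 adjusted over the list alone, adjusted p = 0.0425 with an estimated correlation), as were nitrogen catabolite repression (0 of 30, also adjusted over the list alone) and the phosphate regulon (1 of 19, 2 adjusted over the list alone), both at adjusted p = 0.0244 with an estimated correlation. With spot position corrected the last 2 calls were lost (adjusted p = 0.138 and 0.124), and those of the respiratory chain and sulfate lists held (0.0257 and 0.0336). Camera also called the iron and glycolysis lists lower and the TCA cycle list higher, lost at adjusted p = 0.133 or more with an estimated correlation. The count was 20 genes, 15 higher and 5 lower (155 at an unadjusted p under 0.05), and 11 were Ty frames. It was 4 without M13 replicate 1 (2 higher and 2 lower), 7 without replicate 2 (4 and 3) and 14 without replicate 3 (9 and 5). The calls of ATP8 and CYC1 ended without each of the 3 (adjusted p up to 0.631 and 0.787), that of PDR15 without replicate 1 or 2 (1.00), and those of MET6 and YDR034C-C without replicate 1 (0.999 and 0.309). Without replicate 1 of every strain 0 genes passed, so that the calls of PHO84 and MRH1 ended too (adjusted p = 0.228 and 0.119). With arrays scaled to an equal spread 38 genes were higher and 23 lower, and with spot position corrected 31 and 13.

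In YPS163 the mitochondrially encoded genes ATP8 and ATP6 were higher by 3.71 ± 0.48 (SE, adjusted p = 6.52e-06) and 2.38 ± 0.46, while AI4, encoded in a mitochondrial intron, was lower with -2.45 ± 0.41. Of its 17 genes past the threshold 6 are mitochondrially encoded, against 3 in S288C, 2 in M13 and 2 in M34, counted after the calls were seen and not tested. RDL1 was lower with -2.28 ± 0.42, the sulfite pump gene SSU1 with -1.86 ± 0.42, and the small heat shock gene HSP42 was higher by 1.15 ± 0.25. In the heat shock list 1 of 30 genes was higher, 4 adjusted over the list alone, and its camera call was lost at adjusted p = 0.411 with an estimated correlation. The ribosomal protein list had a median of -0.53 with 0 of 52 genes past the test, and amino acid synthesis one of -0.34 with 0 of 57. Adjusted over the list alone 0 and 4 were lower, and both camera calls were lost at adjusted p = 0.411 with an estimated correlation. Camera also called the sulfate, ribosome biogenesis, glycolysis, sterol and histone lists lower and the stress and respiratory chain lists higher, lost at adjusted p = 0.411 or more with an estimated correlation. The count was 17, with 12 higher and 5 lower (468 at an unadjusted p under 0.05). It was 9 (4 higher and 5 lower), 27 (15 and 12) and 8 (5 and 3) without YPS163 replicate 1, 2 and 3. ATP8 passed in all 15 settings. The calls of ATP6 and HSP42 ended without replicate 3, that of HSP42 also without replicate 1 (adjusted p up to 0.247 and 0.947), those of AI4, RDL1 and SSU1 without replicate 2 (0.0656, 0.0915 and 0.233), and that of SSU1 also without replicate 3. Without the channel effect ATP6, HSP42 and SSU1 did not pass, and HSP42 did not without centring. The split of higher and lower genes was 6 and 5 without centring, 18 and 16 with arrays scaled to an equal spread, 30 and 48 with only the copper arrays, and 29 and 31 with spot position corrected.

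In M34 ATP8 was lower with -3.05 ± 0.48 (SE, adjusted p = 3.21e-04) and ATP6 with -1.99 ± 0.46. YER138W-A, a gene of unknown function, was higher by 3.02 ± 0.40 and the Ty frame YBL005W-B by 2.45 ± 0.54, and 8 of 12 genes past the threshold were Ty frames. In the heat shock list 0 of 30 genes passed, 3 were higher adjusted over the list alone, the median was 0.46, and the camera call was lost at adjusted p = 0.107 with an estimated correlation. The stress and respiratory chain lists were called higher too, and both calls were lost with an estimated correlation. Of the 12 genes 10 were higher and 2 lower (184 at an unadjusted p under 0.05). The count was 3, 3 and 6 without M34 replicate 1, 2 and 3, and the calls of ATP6 and YBL005W-B ended without each of them, that of ATP6 also without centring or the channel effect (adjusted p up to 1.00 and 0.871). Without replicate 1 of every strain 0 genes passed, which ended the calls of ATP8 and YER138W-A as well (adjusted p = 0.388 and 0.075). The count was 7 without centring, 20 with only the copper arrays and 21 with spot position corrected.

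In M5 the flocculin genes FLO9 and FLO1, which share sequence and count as uncertain, were higher by 2.10 ± 0.33 (SE, adjusted p = 7.49e-04) and 2.04 ± 0.37, and the sulfite pump gene SSU1 by 1.91 ± 0.42. The cell wall mannoprotein gene HPF1 and its relative CSS1 were lower with -2.22 ± 0.41 and -2.50 ± 0.43. The respiratory chain list was lower with a median of -0.53, 0 of 40 genes by themselves and 13 adjusted over the list alone (camera adjusted p = 0.00338 with an estimated correlation). The TCA cycle and the nitrogen catabolite repression lists were called lower as well (both adjusted p = 0.0251 with an estimated correlation, 0 of 30 genes each, also adjusted over the list alone). These 2 calls were lost with spot position corrected (adjusted p = 0.0719 and 0.143), with the median of the nitrogen list going from -0.19 to -0.06, and that of the respiratory chain list held (0.0349). The trehalose and general stress list had a median of -0.43, and its camera call was lost at adjusted p = 0.0724 with an estimated correlation. Further camera calls were the heat shock, ribosome biogenesis, sterol and vitamin lists (higher), lost at adjusted p = 0.0724 or more with an estimated correlation. The count was 6 genes, 4 higher and 2 lower (205 at an unadjusted p under 0.05). It was 3, 0 and 7 without M5 replicate 1, 2 and 3. Without replicate 2 the calls of FLO9, FLO1, SSU1, CSS1 and HPF1 ended (adjusted p up to 0.121, 0.309, 0.309, 0.135 and 0.199), and those of CSS1, HPF1 and SSU1 also without replicate 1, and that of SSU1 without replicate 3 or the channel effect. The split of higher and lower genes was 7 and 7 with arrays scaled to an equal spread, 6 and 14 with only the copper arrays, and 7 and 6 with each array centred by block of rows.

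M8, M14 and M22 each had 2 genes past the threshold. The Ty frame YJR027W was lower in all of them, with -1.88 ± 0.38 in M8, -2.09 ± 0.38 in M14 and -1.87 ± 0.38 in M22. YPL257W-B was lower in M8 (-2.09 ± 0.42), MRH1 in M14 (-1.80 ± 0.34), and YLR179C, an uncharacterized gene, was higher in M22 (1.21 ± 0.25). The sulfate assimilation list was higher in M14 with a median of 0.38 (0 of 31 genes, 5 adjusted over the list alone, camera adjusted p = 0.0435 with an estimated correlation) and in M22 with 0.63 (0 of 31, 10 adjusted over the list alone, the call being lost at adjusted p = 0.054 with an estimated correlation). With spot position corrected this list had a median of 0.42 in both, and with an estimated correlation the call held in M14 and was gained in M22 (adjusted p = 0.012 and 0.00527). In M8 the heat shock list had a median of -0.22, and its call was lost at adjusted p = 0.201 with an estimated correlation. Its stress, oxidative stress and respiratory chain lists were also called lower and its meiosis, ribosomal protein and hexose lists higher, lost at adjusted p = 0.201 or more with an estimated correlation. In M14 camera called the hexose, mating type, ribosomal protein, amino acid and vitamin lists higher and the heat shock and stress lists lower, lost at adjusted p = 0.0586 or more with an estimated correlation. The hexose call in M14 (median 0.29, 0 of 35 genes, adjusted p = 0.0586 with an estimated correlation) was gained at adjusted p = 0.0352 with spot position corrected. In M22 the zinc, ribosomal protein, sterol and amino acid lists were called higher and the stress list lower, lost at adjusted p = 0.322 or more with an estimated correlation. Each of the 6 gene calls ended without each replicate of its strain in turn, with counts of 0 in every such fit (adjusted p up to 1.00 for YJR027W in M8, 1.00 in M14 and 0.994 in M22, 1.00 for YPL257W-B, 1.00 for MRH1 and 0.994 for YLR179C). At an unadjusted p under 0.05 limma gave 133, 88 and 336 genes, where chance gives 276.2. The numbers in M8 and M14, like those in M5, M13 and M34, lay below it, so these p-values may be inexact. Without centring the counts were 0, 0 and 1, and with spot position corrected 8, 3 and 0, so both M22 calls ended there (adjusted p = 0.264 for YJR027W and 0.0551 for YLR179C).

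In rich medium YGR201C again had the largest range, 8.0 between M32 and M13 (adjusted p = 4.00e-09). It was followed by the Ty frame YBL005W-A (4.86), PHO84 (4.69, between S288C and M13), ATP8 (4.65, between YPS163 and M34), the Ty frame YJR027W (4.56), YER138W-A (4.48) and YHB1 (4.16, between M13 and M32). ASP3-3 ranged over 3.74 between M32 and M5. AQY2, the water channel gene, was highest in YPS163 (range 3.01, adjusted p = 0.0069), where it was 2.34 ± 0.44 above the other strains. The zinc transporter gene ZRT1 ranged over 3.65 between M5 and S288C (adjusted p = 0.048) and passed in 13 of 39 settings (adjusted p up to 0.356). YBL005W-A and YJR027W were highest in S288C. The cold shock mannoprotein genes TIR1 and TIR2 ranged over 2.73 and 2.74, FLO9 over 2.49 with M5 highest, and the sterol gene HMG1 over 1.85 with S288C lowest. In rich medium PHO84 was 3.33 ± 0.37 higher in S288C than in the other 8 strains and YGR201C 6.82 ± 0.62 higher in M32.

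In the lists in rich medium, 3 of 30 nitrogen catabolite repression genes passed (the asparaginase copies ASP3-3 and ASP3-4 among them), 6 adjusted over the list alone. In the phosphate regulon 2 of 19 passed (PHO84, SPL2), also 6 adjusted over the list alone, in the respiratory chain 2 of 40 (CYC1, RIP1) and in the anaerobic list 2 of 19 (TIR1, TIR2). Fisher's exact test gave an adjusted p of 0.313 for the phosphate regulon. CYC1 passed in 15, ASP3-4 in 21 and RIP1 in 34 of 39 settings (adjusted p up to 0.571, 0.418 and 0.478), and CYC1 did not pass with the robust step or without the channel effect. After position correction the same exact test gave an adjusted p of 0.00277 for the phosphate regulon (5 of 19 genes past), 0.00755 for the respiratory chain (6 of 40), and 0.0107 for the cell wall list (5 of 33). Ion transport had the same value (4 of 20), but 3 of these genes are the copies ENA1, ENA2 and ENA5, which may be 1 signal. The test over strains passed 90 of 5524 genes (660 at an unadjusted p under 0.05), and 45 of them were Ty frames. Leaving out all arrays of replicate 1 brought the count to 24, leaving out M32 rich replicate 2 to 150 and YPS163 rich replicate 2 to 176. With arrays scaled to an equal spread it was 57, with only the rich arrays 50, and with spot position corrected 148, of which 76 were shared. Of the genes named here, AQY2 lost its call without YPS163 rich replicate 1 (adjusted p up to 0.279 over the settings), ASP3-3 without M32 or S288C rich replicate 1 (0.409), FLO9 without M5 rich replicate 2 or 3 (0.698), HMG1 without S288C rich replicate 2 (0.245) and TIR2 without M32 rich replicate 1 or 3, without M14 rich replicate 3 or with spot position corrected (0.478). With scaled arrays the calls of AQY2, ASP3-3, ASP3-4, FLO9, RIP1, TIR1, TIR2, YHB1 and ZRT1 ended, with only the rich arrays those of AQY2, CYC1, FLO9, HMG1, RIP1 and ZRT1, and without centring those of ASP3-4, CYC1, HMG1 and RIP1. Leaving out a replicate number of every strain ended the calls of FLO9, HMG1 and ZRT1 (numbers 1, 2 and 3), ASP3-3, ASP3-4 and CYC1 (1 and 2), RIP1, TIR1 and TIR2 (1 and 3), and AQY2, SPL2 and YHB1 (1).

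Strain differences in the 2 media overlapped. Of 80 genes past the test in copper and 90 in rich medium 55 were shared, where independent lists would share 1.30 (Fisher's exact test, two-sided, p = 8.76e-88). Both tests came from 1 fit with 1 estimate of spread per gene. Ty frames, many with shared hybridization, made up 32 of the 80 and 45 of the 90. The lists and their genes are thus not independent, and this p overstates the evidence. In S288C 40 genes passed in both media, all 40 in the same direction. Across the 115 genes past either test, the strain differences in copper and in rich medium correlated between 0.61 in M22 and 0.93 in M13. These are correlations across genes, which are not independent replicates, and the genes were chosen for differing. Over all 5524 genes the same correlation was -0.43 in M22, -0.14 in M8, 0.00139 in YPS163, 0.15 in M14 and between 0.31 and 0.72 in the other strains, and with spot position corrected it ran from 0.28 in M22 to 0.74 in S288C. Of the genes that differed among strains in copper 4 were also past the test in the pools, where chance gives 1.13 (p = 0.0259 by Fisher's exact test).

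**Figure D3:**
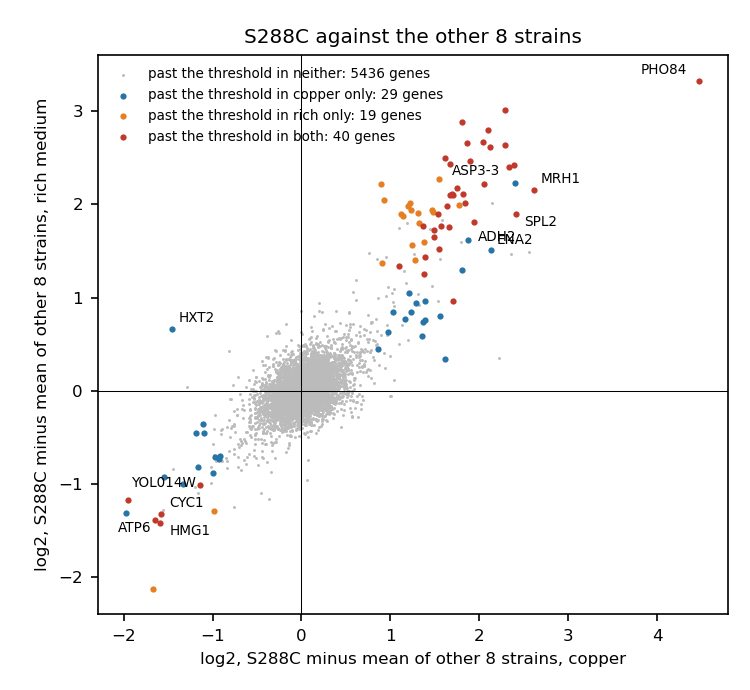
Log2 difference of S288C from the mean of the other 8 strains in copper (horizontal) and in rich medium (vertical), with 1 point per gene. The 40 genes past the test in both media have the same sign in both, with PHO84 highest at 4.47 in copper and 3.33 in rich medium.

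A test of whether the strain differences change with the medium passed 0 of 5524 genes by limma, with 261 at an unadjusted p under 0.05 where chance gives 276.2. The metallothionein copies CUP1-1 and CUP1-2 had ranges of 2.04 and 2.41 between the responses of strains (adjusted p = 0.879 and 0.875), and CRS5 1.24 (0.873). Without M32 rich replicate 2, 1 gene passed. In simulated data with independent noise and a change in 1 strain, 0% of such differences of log2 1 and 50% of log2 2 were recovered. A difference of log2 1 in 1 strain was thus not detectable, and other patterns over strains were not simulated. Within strains, where the value also rests on the direction of the pool arrays, CUP1-1 rose in copper by between 4.98 ± 1.05 in YPS163 and 6.82 ± 1.06 in M5 in 7 strains. In M13 and S288C it had values of 4.86 and 4.97 that did not pass (adjusted p = 0.149 and 0.0532). With spot position corrected CUP1-1 passed in both (adjusted p = 0.0047 and 0.00433).

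Cell type markers did not separate the strains. STE2, the receptor gene of MATa cells, ranged over 1.2 in copper and 1.66 in rich medium (adjusted p = 1.00 and 0.0832), and STE3, its counterpart in MATalpha cells, over 1.43 in copper and 1.87 in rich medium (adjusted p = 1.00 and 0.317). MF(ALPHA)1, a pheromone gene, ranged over 0.64 in copper and 0.72 in rich medium, and HO, the mating-type switching endonuclease gene, over 1.29 in copper and 1.15 in rich medium (adjusted p = 1.00 and 0.806). By limma 0 of 28 genes in the mating-type list and 0 of 30 in the meiosis list passed in either medium, also adjusted over each list alone. Because each array compares a strain with a pool of all strains, these values do not give the absolute level.

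Pairwise correlations of strain profiles, a comparison made after the values were seen, were taken across the 200 genes that varied most in the other medium, with spot position corrected. M14 and M22 correlated at 0.84 in copper and 0.74 in rich medium, M8 and M14 at 0.81 and 0.72, and M8 and M22 at 0.81 and 0.62. The next pair, M32 and M34, had 0.28 and 0.33. S288C and M8 had the lowest values, -0.73 and -0.64. Genes are not independent replicates in these correlations. Ty frames, many with shared hybridization, were not left out of the 200 genes, so 1 signal may weigh several times.

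**Figure D4:**
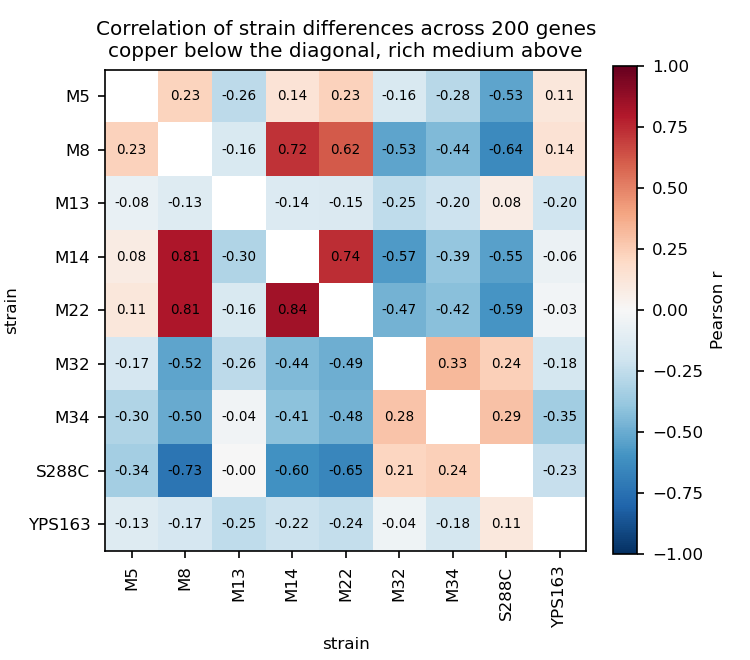
Pearson correlation across 200 genes between the profiles of each pair of strains, copper below and rich medium above the diagonal. M8, M14 and M22 form the only pairs above 0.5 in both media.

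**Figure D5:**
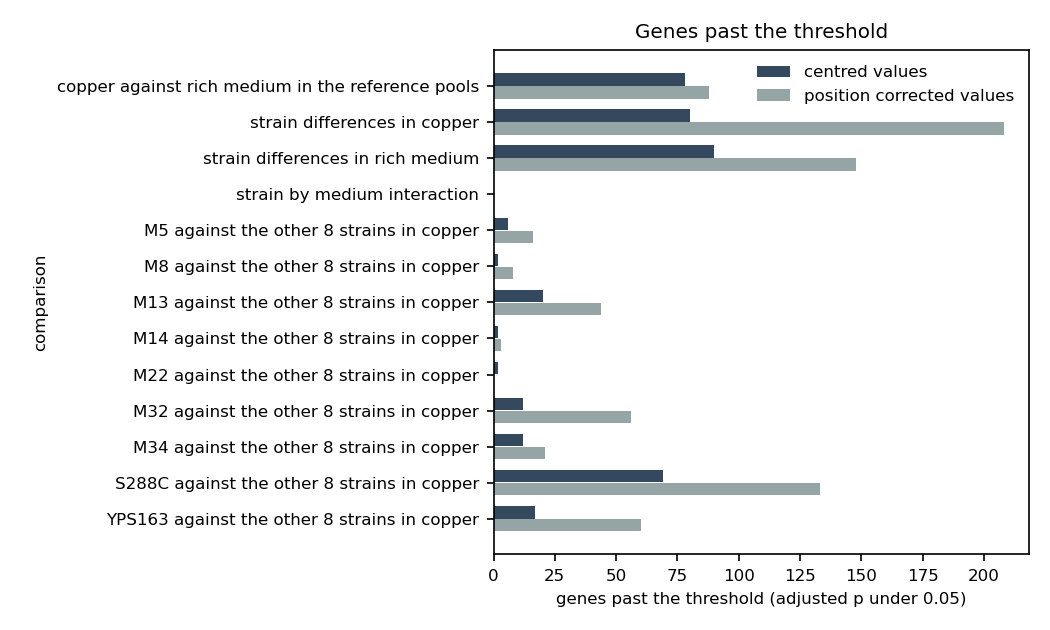
Number of genes past the adjusted threshold in each comparison, with centred values and with values corrected for spot position. S288C has the most genes of any strain in copper, 69 and 133.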

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

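The regroupings of position-corrected values, the test of spot position for M8, the tests on S288C and the test of slower growth were chosen after the results were seen. The position correction itself was chosen after the data were seen, so the tests of spot position on the stress genes and of a broad difference in M8, which use it, were not planned either, although their bounds were set before their values were read. The other tests were planned.

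SOD1 on pool array 4 lay far from the other arrays, with a log2 value of -0.01 against 1.22 to 1.91. Its gap to the nearest array was 0.640 of the range over 6 arrays, past the critical value of the Dixon gap test. It was the 1 of 22 named genes and 3 array measures past that value. Chance flags about 1 in 20 groups. No biological explanation was tested.

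Among the 603 rows with no listed gene, which the comparisons leave out, 1 passed the threshold in the pools, 5 in the strain differences in copper and 7 in those in rich medium. These were 0.17%, 0.83% and 1.16% of such rows, each a lower share than the 78, 80 and 90 of 5524 named genes. What these rows measure was not analysed here.

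In M8 in rich medium 2089 genes had an unadjusted p under 0.05, against 279 with spot position corrected and 276.2 expected by chance. The SD of the M8 differences over all genes fell from 0.61 to 0.24. The 8 genes past the threshold had a median absolute log2 of 1.69 (median SE 0.35) before and 1.10 (0.32) after, with a lowest adjusted p of 0.0817, so these calls ended through smaller differences. Spot position may thus explain most of this pattern. A broad expression difference of M8 stays open, since its differences in copper and rich medium correlated at 0.428 across genes after correction (-0.138 before). In the other strains the same correlation ran from 0.279 to 0.742, so it does not set M8 apart, and genes are not independent replicates.

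Of the 69 genes that set S288C apart in centred values, 24.6% were lower. This argues against S288C sequence on the array as the whole cause, since better hybridization raises values. The share depends on centring. Without it 51 of 60 genes were lower, but the median of all genes was then -0.48, so that count adds nothing to the argument. For the 52 higher genes the difference in rich medium divided by that in copper had a median of 1.03, so sequence or copy number, which would not change with the medium, may account for part of them. A difference in expression stays open as well, and copy number was not tested. All 69 genes (100%) stayed past the threshold after position correction, which argues against spot position as the cause. The layout is inferred and patterns finer than the window of 15 by 15 spots would remain, so spot position is not excluded.

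The 24 stress and chaperone genes that rose in the copper pool lay above 0 in both channel orders in 100% of cases. They were chosen for a rise on the same arrays in a fit that removes the channel effect. This outcome was thus largely set by the choice and is no independent test of that effect. After position correction 95.8% (23 of 24, all but YDJ1) stayed past the threshold, which argues against spot position. Slower growth in copper cannot be told apart from a stress response here: the ribosomal protein list had a median of -0.17, below 0 but not past the test with an estimated correlation. Growth rates are not analysed here.

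Regrouping the arrays tested whether chance assignment could give as many genes. For the 6 pool arrays only 15 splits exist, too few for a share under 0.05; the real split, 1 of them, gave 78 genes and the highest other 0. With 100 groupings, the real one included, the share as large was under 0.05 for the strain differences in copper (80 genes, highest other 14, 1 grouping as large). The same held for M13 (20, 10, 1), M32 (12, 35, 3), M34 (12, 14, 2), S288C (69, 3, 1) and YPS163 (17, 5, 1). These shares were not adjusted over the comparisons, and the regroupings did not hold the replicate number fixed, so chance is made less likely but not excluded. The share was 0.05 or more for rich medium (90 genes, highest other 2131, 7 groupings as large), M5 (6, 90, 5), M8 (2, 17, 7), M14 (2, 22, 9) and M22 (2, 78, 7). For the interaction the regroupings decide nothing, since with 0 genes (by limma, with 261 at an unadjusted p under 0.05) all 100 groupings are as large by construction, the highest other giving 311. Groupings with several times the real count, such as those with 2131 genes in rich medium, 90 in M5 and 78 in M22, point to a structure of the samples whose cause was not tested.

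With position-corrected values the share was under 0.05 for the strain differences in copper (208 genes, highest other 47, 1 grouping as large) and in rich medium (148, 70, 1). The same held for M5 (16, 35, 3), M13 (44, 89, 2), M32 (56, 173, 3) and S288C (133, 119, 1). The share was 0.05 or more for M8 (8, 64, 8), M14 (3, 58, 17), M34 (21, 247, 5) and YPS163 (60, 524, 5). The outcome for M34 and YPS163, and for M5 and rich medium, thus differs from that with centred values. For M22 the regroupings decide nothing, since with 0 genes (by limma, with 284 at an unadjusted p under 0.05) all 100 are as large, the highest other giving 267. The highest other grouping was lower than with centred values in rich medium and M5 and higher in the rest of these comparisons. Groupings with several times the real count point here too to a structure of the samples, and its cause was not tested.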

How the results depend on the processing

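The position correction and the block centring were chosen after the data were seen, and the other alternatives were planned. A count is said to move when it changes by more than 1.5 times. For moved counts the cause was not tested, except where construction is named. Missing-value alternatives were not run, since 0 values were missing. The robust step and each row on its own moved 0 of 13 counts. Of the 147 calls of named genes, those with a sign kept it in the alternatives run. Ranges over strains have no sign and could not reverse. Many signed calls had been named because their arrays agreed in side, which favours this outcome.

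Without centring the moved counts were 0 in M8, 0 in M14, 1 in M22, 7 in M34 and 11 in YPS163. With arrays scaled to an equal MAD they were 27 in the pools, 244 for strain differences in copper, 57 in rich medium, 14 in M5, 30 in M8, 61 in M13, 4 in M14, 1 in M22, 80 in M32, 127 in S288C and 34 in YPS163. The 30 genes in M8 were 3 higher and 27 lower. Without a channel effect they were 21 in the pools, 0 in M8 and 8 in YPS163.

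With a replicate block the counts were 139 for strain differences in rich medium, 10 in M5, 4 in M8 and 30 in YPS163. By the labels, number 1 has the strain RNA in channel 2, and numbers 2 and 3 in channel 1, except M5 in rich medium, replicate 3. They do not say what else a number shares. Not every pair of different strains with the same number had a correlation over 0.1, so the numbers were not taken to pair arrays. Of 108 such pairs 81 were over 0.1 in copper and 67 in rich medium. The median correlation across genes was 0.24 and 0.20, with lows of -0.36 and -0.63, against -0.13 and -0.09 for different numbers. Of 27 arrays 23 in copper and 20 in rich medium correlated best with arrays of their own number, and 26 and 25 with spot position corrected. This points to a source of variation shared by arrays with the same number. The channel effect was not removed from these correlations, so channel order may give part of the pattern. It cannot give all of it, since numbers 2 and 3 share an order, with the exception named. The main fit has no term for the number, so its p-values treat these arrays as independent. With the block 113 genes passed for strain differences in copper and 94 in S288C. The regroupings of strain labels did not hold the number fixed.

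With only the arrays of that medium the counts were 143 for strain differences in copper, 50 in rich medium, 20 in M5, 4 in M8, 1 in M22, 20 in M34, 111 in S288C and 78 in YPS163. With spot position corrected they were 208, 148, 16 in M5, 8 in M8, 44 in M13, 0 in M22 (284 at an unadjusted p under 0.05 by limma), 56 in M32, 21 in M34, 133 in S288C and 60 in YPS163. With block centring they were 172, 152, 13 in M5, 5 in M8, 39 in M13, 1 in M22, 31 in M32, 24 in M34, 117 in S288C and 39 in YPS163.

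Without replicate 1 of every strain, 18 genes passed for strain differences in copper and 24 in rich medium, 0 in M8, 0 in M13, 0 in M14, 0 in M22, 1 in M32, 0 in M34, 14 in S288C and 10 in YPS163. By construction this leaves M5 in rich medium, replicate 3, as the only array of the other channel order. Without replicate 2 of every strain the counts were 1 in M5, 5 in M8, 9 in M13, 5 in M14, 1 in M22, 30 in M32, 28 in S288C and 34 in YPS163. Without replicate 3 of every strain they were 51 for strain differences in copper, 0 in M5, 0 in M8, 13 in M13, 0 in M14, 0 in M22, 5 in M34, 27 in S288C and 8 in YPS163.

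Leaving out single arrays gave counts of 15 to 89 in the pools, 70 to 176 for strain differences in rich medium, 0 to 1 for the interaction, 0 to 7 in M5, 0 in M8, 4 to 14 in M13, 0 in M14, 0 in M22, 1 to 41 in M32, 3 to 6 in M34, 18 to 32 in S288C and 8 to 27 in YPS163. Where it leaves a group with fewer arrays, these are assumed to vary like the other groups.

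Of 147 calls of named genes, 125 held with arrays scaled to an equal MAD, 138 with spot position corrected, 142 with block centring, 117 without the channel effect, 112 without centring, 144 with the robust step and 147 with each row on its own. Of the calls in strain arrays 103 held with only the arrays of that medium, with 19 lost, and 121 with the replicate block, with 1 lost, that of FLO9 over strains in rich medium (adjusted p = 0.138). Over all fits without 1 replicate, 1836 held and 486 did not. Of 77 camera calls of lists 13 held with an estimated correlation and 71 with spot position corrected.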

Other observations

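Further genes passed the test in the pools and are named here after their values were seen, without a test of any group. PRE8, PRE10 and PUP2, which encode subunits of the proteasome core, rose by 0.87, 0.90 and 0.89, and UBA1, the ubiquitin activating enzyme gene, by 0.87. The glutaredoxin genes GRX1 and GRX2 rose by 0.80 and 0.71, and GRX5, which acts in mitochondrial iron and sulfur cluster assembly, fell with -0.90.

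In YPS163 the mitochondrially encoded COX1 and VAR1 were higher than in the other strains by 2.37 and 2.23, and the endoplasmic reticulum oxidase gene ERO1 by 1.55. In S288C the dihydroorotate dehydrogenase gene URA1 was higher by 1.68 and the serine deaminase gene CHA1 by 1.23.

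The tests of strain resemblance and chromosome medians were chosen after the values were seen. The bounds of the Hap1 test were set before its values were read, but its genes were limited to those not past the threshold in S288C. A hypothesis is that M8, M14 and M22 are closely related. The pairwise correlations of the 9 strains in copper followed those in rich medium over 36 pairs (r = 0.936, rho = 0.889, one-sided permutation p = 4e-05), which is consistent with stable differences between strains, though relatedness itself was not measured.

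A further hypothesis is a lower activity of the heme activator Hap1 in S288C, which is known to carry a Ty insertion in HAP1. Over 5 measured Hap1-activated genes (CYT1, CYB2, CYC7, CCP1 and OLE1) the median difference of S288C in copper was -0.17, with 3 of 5 below 0. The one-sided p against random sets was 0.0529 (permutation test). Genes past the threshold in S288C were left out of this set by their values, so it cannot decide the hypothesis. An extra or missing chromosome in a strain would shift a whole chromosome. The largest absolute chromosome median of any strain was 0.13 after block centring and 0.11 before, far below such a shift.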
